A study of Homo sapiens with 11 samples.

How the data were processed

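RNA levels were measured in untreated MCF-7 (4 arrays), MCF-7:5C (3) and MCF-7:2A (4) cells. Per the labels' protocols, cells grew in oestrogen-free medium, RNA was extracted with Trizol, and biotinylated cRNA was made from 6 ug of total RNA and hybridized to arrays of the Affymetrix U133 Plus 2.0 type. The deposited values are linear probe set intensities, made by the authors with MAS5 per the submitters' processing notes, with no version given in the sources used here. No detection calls were used here. Every array but 1 had a 2% trimmed mean of 500 in the deposited values, while MCF-7:2A replicate 2 had 188.8. The design fixed in advance took the deposited values without further scaling, on the premise that all arrays were scaled alike. Because this premise failed for 1 array, all arrays were rescaled to a 2% trimmed mean of 500 (a factor of 2.65 for that array), which had been listed as an alternative. This was decided after the array totals were seen and before any test, and the counts on the deposited scale are given beside the main ones.

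Of 54675 probe sets, 62 controls were left out. The annotation of the platform gave 1 gene for 41097 probe sets, several for 1801 and none for 11777 (controls included), and probe sets without a single gene were not named. Symbols were updated through the Entrez identifier for 41043 of the 41097. Probe sets with a mean log2 value under the 40th percentile (a scaled signal of about 93.3) were left out, which kept 32768 probe sets, 26323 of them with 1 gene. Each gene was represented by its probe set with the highest mean, giving 14150 genes. In MCF-7:5C against MCF-7, 622 genes had probe sets called in opposite directions. Values were analysed as log2(value + 16), so fold changes of dim genes are understated, and the size of a difference with 1 group under the filter level depends on the background and the pseudocount. No genome build is named for the values, so no coordinates are given; NCBI RefSeq genes of the assembly GRCh38.p14 served only for symbols and for the order of neighbouring genes.

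Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend) in 1 model of 3 group means over all 11 arrays, two-sided, with Benjamini-Hochberg adjustment over the genes tested. Genes with an adjusted p under 0.05 are called changed. The 22 gene lists (type I interferon response, cell cycle, cell cycle inhibitors and p53 targets, apoptosis regulators, unfolded protein response, oestrogen response targets, nuclear receptor coregulators, steroid synthesis and oestrogen metabolism, growth factor receptors and ligands, luminal identity, basal epithelial markers, mesenchymal transition, cell junctions, carcinoembryonic antigen family, antigen presentation, inflammatory cytokines, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis and storage, glutathione and oxidative stress, extracellular proteases and inhibitors, and stromal and immune cell markers) were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists. Camera with an estimated correlation and fry were alternatives. The design, the lists and the rule for named genes were fixed before the data were examined. The rule named the 6 largest rises and 6 largest falls per comparison with MCF-7 among non-overlapping groups changed at least 2-fold, and up to 4 members of each list past camera or 1 of each other list. For MCF-7:5C against MCF-7:2A it named 4 rises, 4 falls and up to 3 members of lists past camera. It also named 3 shared genes per direction, and ESR1, PGR, TFF1, CEACAM5 and CEACAM6 in every comparison. The gene named as lowest or highest in a list is not a summary of that list.

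The method was tested on simulated data with 200 genes changed by known amounts among 14150. A further short list shifted by 0.5 log2 units was also counted as changed. For MCF-7:5C against MCF-7, 29.9% of genes changed by 0.5 log2 units, 73.1% of those changed by 1 and 98.5% of those changed by 2 were recovered, and 4.08% of calls were unchanged genes. For MCF-7:2A the shares were 37.3%, 74.6%, 100% and 3.27%, and for MCF-7:5C against MCF-7:2A 23.9%, 71.6%, 93.9% and 4.35%. The simulated genes were independent, and far fewer of them changed than the 48.6% to 54.4% called in the data. These shares need not hold for the real fits. Alternatives covered the scaling (deposited, quantile, median), pseudocounts of 1 and 64, the brightness filter (none, 60th percentile), the choice of probe set, the variance prior, the arrays in the fit, a replicate block and leaving out each array. List counts without MCF-7:2A replicate 2 were chosen after seeing the data.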

Results

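Messenger RNA levels were measured with 11 whole-transcriptome Affymetrix arrays (type U133 Plus 2.0) in 3 groups of cultured human breast cancer cells. MCF-7 is an oestrogen receptor-positive breast cancer cell line, and MCF-7:5C and MCF-7:2A are sublines of it kept without oestrogen. The groups held 4 arrays of wild-type MCF-7, 3 of MCF-7:5C and 4 of MCF-7:2A, which the labels call biological replicates. All cells were untreated and were grown in the same oestrogen-free medium with 10% charcoal-treated serum. P-values measure the spread between these arrays, and the small number of arrays limits the precision. Of the 54675 probe sets, 14150 genes were tested after filtering. Pearson correlations of log2 signals were 0.929 to 0.971 between arrays of the same group and 0.867 to 0.918 between arrays of different groups. These are correlations across probe sets, which are not independent replicates. The arrays had been scaled to a common 2% trimmed mean. After this scaling the median signal was 171 ± 11.4 (SD, n = 4) in MCF-7, 118 ± 3.93 (SD, n = 3) in MCF-7:5C and 163 ± 6.38 (SD, n = 4) in MCF-7:2A. The log2 ratio of the 3' to the 5' actin control probe sets, a sign of RNA quality, was 0.44 ± 0.10 (SD, n = 4) in MCF-7, 0.10 ± 0.09 (SD, n = 3) in MCF-7:5C and 0.19 ± 0.09 (SD, n = 4) in MCF-7:2A. The median was lower in MCF-7:5C, while those of MCF-7 and MCF-7:2A overlapped, and the actin ratio was lower in both sublines than in MCF-7. The same ratio of the GAPDH control probe sets was -0.168 ± 0.148 (SD, n = 4) in MCF-7, -0.174 ± 0.013 (SD, n = 3) in MCF-7:5C and -0.07 ± 0.065 (SD, n = 4) in MCF-7:2A.

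The oestrogen receptor gene and 4 other genes were fixed for every comparison. ESR1, which encodes oestrogen receptor alpha, was higher in both sublines, with a scaled signal of 6047 ± 1770 (SD, n = 4) in MCF-7, 14760 ± 607 (SD, n = 3) in MCF-7:5C and 21950 ± 1240 (SD, n = 4) in MCF-7:2A. One ESR1 probe set out of 7 others fell in MCF-7:5C, while 4 rose. PGR, the progesterone receptor gene and a known oestrogen target, fell in MCF-7:5C and rose in MCF-7:2A. Its log2 difference from MCF-7 was -1.81 ± 0.44 (SE, adjusted p = 0.00264) in MCF-7:5C and 2.36 ± 0.41 (SE, adjusted p = 0.000203) in MCF-7:2A. CEACAM6, a cell surface glycoprotein gene, rose by 4.51 ± 0.15 (SE) log2 units in MCF-7:5C and by 3.33 ± 0.14 (SE) in MCF-7:2A. CEACAM5, of the same family, differed by -0.79 (adjusted p = 0.00739) and -0.68 (adjusted p = 0.013, with overlapping groups). Its call in MCF-7:5C was lost on the deposited scale (an unchanged -0.79, adjusted p = 0.107), under median centring (-0.305, adjusted p = 0.322) and with the mean of its probe sets (-0.43, adjusted p = 0.0569). TFF1, a secreted oestrogen-induced peptide gene, differed by 0.48 (adjusted p = 0.000285) in MCF-7:5C and 0.84 (adjusted p = 7.86e-07) in MCF-7:2A. The first of these calls was lost under quantile normalization (0.19, but 0.96 under median centring). Both were lost on the deposited scale, with an unchanged 0.48 (adjusted p = 0.38) in MCF-7:5C and 0.49 (adjusted p = 0.329) in MCF-7:2A.

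**Figure D1:**
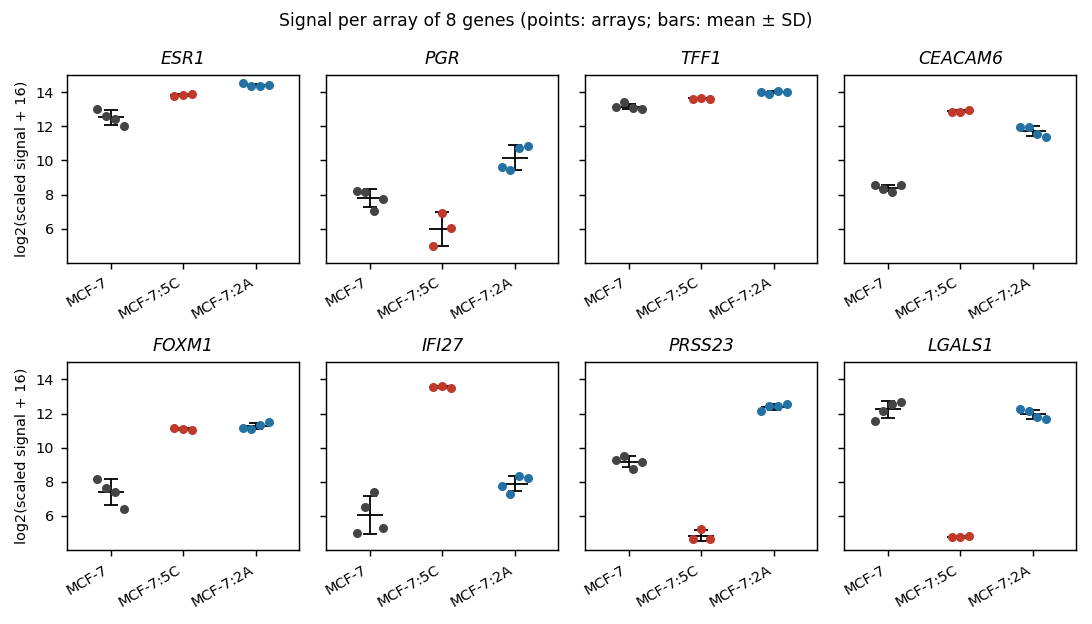
Each panel shows log2 of the scaled signal plus 16 for 1 gene, with a point per array and the mean ± SD per group (4 MCF-7, 3 MCF-7:5C and 4 MCF-7:2A arrays). IFI27 lies at 13.50 to 13.62 on the MCF-7:5C arrays and at most at 8.32 on the others, while LGALS1 and PRSS23 are lowest in MCF-7:5C.

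The comparison of MCF-7:5C with wild-type MCF-7 addresses how the expression profile of this subline differs in the same medium. Interferon-induced genes and cell cycle genes were higher in MCF-7:5C, while genes of growth arrest and of the unfolded protein response were lower by the test with a preset correlation. These last 2 calls were lost (adjusted p = 0.0962 each with an estimated correlation). IFI27, an interferon-induced gene, had a scaled signal of 12020 ± 495 (SD, n = 3) in MCF-7:5C and 66.9 ± 63.8 (SD, n = 4) in MCF-7, a log2 difference of 7.51 ± 0.44 (SE, adjusted p = 2.72e-09). LGALS1, which encodes galectin-1, had 11.7 ± 1.06 (SD, n = 3) against 5064 ± 1640 (SD, n = 4), a log2 difference of -7.46 ± 0.22 (SE, adjusted p = 6.52e-12). Of 14150 genes, 7703 changed, of which 3805 rose and 3898 fell. At least 2-fold, 1579 rose and 1654 fell. The next largest rises were those of MGP (6.12), ADAMTS19 (5.90), SH3BGRL (5.65), BST2 (5.37) and TNFRSF11B (5.36 log2 units). The largest falls after LGALS1 were those of CLIC3 (-6.25), OLFM3 (-5.09), SLC6A14 (-4.87), KRT80 (-4.86) and PDK4 (-4.69 log2 units). The lower signal of all of these genes but BST2 and KRT80 lay under the filter level of 93.3, so the size and order of these differences depend on the background and the pseudocount.

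Of 35 measured genes of the type I interferon response, 32 rose and 0 fell, and 3 did not pass (limma's camera, adjusted p = 3.14e-18, and adjusted p = 0.00433 with an estimated correlation). At an unadjusted p under 0.05, 0 fell as well, and fry gave an upward direction with adjusted p = 5.63e-10. Adjusted over the list alone, 32 rose. Part of this list was of interest in earlier work on these lines, so its direction is not independent evidence. The median difference was 2.55 log2 units, and IFIT1, which binds viral RNA, and IFITM1, a membrane protein gene, rose by 5.25 and 5.02. Of 40 cell cycle genes, 39 rose, 0 fell and 1 did not pass (adjusted p = 1.02e-19, and adjusted p = 0.00958 with an estimated correlation). Adjusted over the list alone, 39 rose, 0 fell at an unadjusted p under 0.05, and fry gave an upward direction with adjusted p = 2.48e-09. FOXM1, a transcription factor of mitosis, rose by 3.71 log2 units, and TYMS, MCM7 and CDC25A, which act in DNA synthesis, DNA licensing and entry into S phase, rose by 2.81, 2.69 and 2.66. Without any 1 of the MCF-7:5C arrays another MCM7 probe set was the brightest, and its difference was 1.17 to 1.32. The lower array medians and actin ratios of MCF-7:5C went along with both lists. Among 9 measured markers of stromal and immune cells, 0 rose and 3 fell, with 0 rising at an unadjusted p under 0.05 (limma; fry downward, adjusted p = 0.000174), and COL1A1, a collagen gene, differed by -2.07 log2 units.

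Further lists passed camera only with the preset correlation. They also passed fry, which does not compare a list with other genes, with adjusted p of 2.29e-05 or less. Of 19 cholesterol synthesis genes, 12 rose and 2 fell, with INSIG1 at 1.68, LSS at 1.51 and ACAT2 at 1.30 log2 units (adjusted p = 0.00495, and adjusted p = 0.0962 with an estimated correlation). Adjusted over the list alone, 13 rose and 2 fell. Of 25 genes of the unfolded protein response, 5 rose and 17 fell (adjusted p = 0.00558, and adjusted p = 0.0962 with an estimated correlation). Adjusted over the list alone, the counts were the same, and the stress-induced genes ATF3, HSP90B1, PPP1R15A and DDIT3 differed by -3.43, -2.36, -2.21 and -1.81. Of 15 cell cycle inhibitors and p53 targets, 2 rose and 10 fell, over all genes and adjusted over the list alone (adjusted p = 0.00869, and adjusted p = 0.0962 with an estimated correlation). GADD45A, GADD45B and CDKN1C fell by 3.59, 2.79 and 2.66 log2 units, while TP53I3 rose by 3.34. Of 23 growth factor receptors and ligands, 2 rose and 14 fell, over all genes and adjusted over the list alone (adjusted p = 0.00869, and adjusted p = 0.122 with an estimated correlation). HBEGF and EGFR differed by -3.16 and -2.21, while FGFR4 and RET rose by 3.43 and 2.18. EGFR differed by -1.46 to -1.42 without MCF-7 replicate 2 or any of MCF-7:2A replicates 1 to 3 and by -0.82 without probe sets ending in _s_at and _x_at, each with another probe set. As the mean of their probe sets, EGFR and HBEGF differed by -1.29 and -1.87. Of 18 luminal identity genes, 12 rose and 3 fell, and 4 fell adjusted over the list alone (adjusted p = 0.00918, and adjusted p = 0.313 with an estimated correlation). PRLR and SPDEF rose by 2.74 and 1.68, and ELF3 fell by 1.80 log2 units. The luminal list did not pass under quantile normalization (adjusted p = 0.153) or with the mean of probe sets (adjusted p = 0.0733). With probe sets ending in _s_at and _x_at left out, these 5 lists did not pass, although their medians moved little. The medians were then 0.532 for cholesterol synthesis (main 0.551), -0.492 for the unfolded protein response (main -0.535) and -0.944 for the inhibitors (main -0.944). They were -0.639 for growth factors (main -0.609) and 0.455 for luminal identity (main 0.495).

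Other lists did not pass. Of 26 oestrogen response targets 4 rose and 9 fell, and PRSS23 fell by 4.33 log2 units. Of 14 genes of steroid synthesis 4 rose and 4 fell, with STS, which frees oestrone from its sulphate, at 3.53, but at 0.91 to 1.07 with another probe set when any of 6 of the 11 arrays (the MCF-7:5C arrays and MCF-7:2A replicates 1 to 3) was left out or with a pseudocount of 1, and at 1.86 as the mean of its probe sets. Of 6 genes of the carcinoembryonic antigen family 3 rose and 2 fell, a family of interest in earlier work on these lines and so not independent evidence (camera passed on the deposited scale, adjusted p = 0.0419). Of 25 apoptosis regulators 4 rose and 10 fell, with PMAIP1 at -3.39. Of 18 proteases and inhibitors 3 rose and 11 fell, with TIMP3 at 4.21. Of 16 genes of antigen presentation 7 rose and 1 fell, with PSMB9 at 2.03. The other lists had 0 of 6 basal markers rising and 4 falling (limma; 0 and 5 at an unadjusted p under 0.05, fry downward with adjusted p = 8e-06, with ANXA1 at -4.09; camera passed on the deposited scale, under quantile normalization and under median centring, with adjusted p = 0.00537, 0.0334 and 0.0369), and 14 of 29 glutathione genes rising and 6 falling (SLC7A11 at -2.49). For 25 hypoxia and glycolysis genes the counts were 8 and 10 (ADM at -2.13), for 19 fatty acid genes 6 and 4 (MLXIPL at -1.99), and for 17 junction genes 7 and 5 (CLDN4 at -2.83). For 12 mesenchymal genes they were 1 and 1 (ITGA5 at -1.20, with overlapping groups and its call lost under quantile normalization), for 20 inflammatory genes 3 and 4 (IL1A at -2.37), and for 19 coregulators 5 and 3 (CARM1 at 1.75).

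The balance of rises and falls depended on the scaling. At least 2-fold, 48.8% of the changed genes rose with the trimmed mean scaling, 58.6% under quantile normalization and 81.8% under median centring. The median over all genes was -0.095, 0.089 and 0.39 log2 units respectively. On the deposited scale 3326 genes changed. As the mean of their probe sets, LSS, SPDEF, PRSS23 and COL1A1 differed by 0.78, 0.99, -2.82 and -1.31, and ATF3 by -1.96 without probe sets ending in _s_at and _x_at.

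The comparison of MCF-7:2A with wild-type MCF-7 asks the same of the other subline. Cell cycle genes were higher in MCF-7:2A, and genes of the unfolded protein response were lower. Known oestrogen targets were higher by camera with the preset correlation, but did not pass with an estimated correlation (adjusted p = 0.252). Fry, which does not compare a list with other genes, gave an upward direction (adjusted p = 2.11e-05). ADAMTS19, a secreted metalloprotease gene, had a scaled signal of 4356 ± 292 (SD, n = 4) against 15.2 ± 12.8 (SD, n = 4) in MCF-7, a log2 difference of 7.21 ± 0.21 (SE, adjusted p = 4.18e-12). OLFM3 had 17.5 ± 9.16 (SD, n = 4) against 1570 ± 632 (SD, n = 4), a log2 difference of -5.51 ± 0.31 (SE, adjusted p = 3.39e-09). In all, 6872 genes changed, of which 3743 rose and 3129 fell. At least 2-fold, 1230 rose and 911 fell. AGR2 (5.99), SH3BGRL (5.96), SLC27A6 (5.74), BPIFB1 (5.48) and EYA2 (5.08 log2 units) followed among the rises. TIMP1 (-4.99), SLC6A14 (-4.85), TFAP2A (-4.61), PPM1J (-4.30) and DKK1 (-4.14 log2 units) followed among the falls. The lower signal of all of these genes but AGR2, TIMP1, TFAP2A and DKK1 lay under the filter level, so these sizes too depend on the background and the pseudocount.

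Of 40 cell cycle genes, 39 rose and 0 fell, also adjusted over the list alone and at an unadjusted p under 0.05 (adjusted p = 9.38e-18, and adjusted p = 0.0187 with an estimated correlation; fry adjusted p = 1.55e-08). FOXM1 rose by 3.87 log2 units, and MCM5, RRM2 and TYMS, which act in DNA replication and nucleotide synthesis, rose by 2.44, 2.32 and 2.30. The lower actin ratio of MCF-7:2A (0.19 against 0.44) went along with these lists. Of 25 genes of the unfolded protein response, 2 rose and 16 fell, or 17 adjusted over the list alone (adjusted p = 7.49e-06, and adjusted p = 0.0187 with an estimated correlation). CHAC1, ATF3, ASNS and HERPUD1, which are induced by stress of the endoplasmic reticulum or by lack of amino acids, differed by -3.48, -3.35, -2.83 and -1.96 log2 units.

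Of 26 oestrogen response targets, 19 rose and 4 fell, over all genes and adjusted over the list alone (adjusted p = 0.000258, and adjusted p = 0.252 with an estimated correlation). PRSS23, SERPINA1 and NRIP1 rose by 3.22, 2.58 and 2.57 log2 units. The SERPINA1 call was lost without MCF-7:2A replicate 3 (0.20, adjusted p = 0.629) and without replicate 4 (0.17, adjusted p = 0.689), and without probe sets ending in _s_at and _x_at (0.14, adjusted p = 0.716), where another probe set was the brightest. Of 25 hypoxia and glycolysis genes 4 rose and 14 fell, with ALDOC, NDRG1, P4HA1 and KDM3A at -1.93, -1.83, -1.80 and -1.75 (adjusted p = 0.00433, and adjusted p = 0.252 with an estimated correlation). Of 15 cell cycle inhibitors and p53 targets 2 rose and 10 fell, with GADD45A at -2.92, CDKN1A at -2.21 and TP53I3 at 2.37 (adjusted p = 0.00907, and adjusted p = 0.108 with an estimated correlation). Of 25 apoptosis regulators 2 rose and 14 fell, among them the cell death promoters PMAIP1, TNFRSF10B and BAX at -2.53, -1.61 and -1.17 (the groups overlap for BAX), while BIK, another, rose by 2.26 (adjusted p = 0.0181, adjusted p = 0.108 with an estimated correlation, and adjusted p = 0.0538 with the mean of probe sets). Of 14 genes of steroid synthesis and oestrogen metabolism 8 rose and 3 fell, with AKR1C3 and STS at 4.05 and 3.63 and CYP1A1 and HSD17B12 at -1.42 and -1.30 (adjusted p = 0.0378, and adjusted p = 0.123 with an estimated correlation). This call was also lost with any of 6 of the 11 arrays left out (adjusted p = 0.0574 to 0.0708), with a pseudocount of 1 (0.0527) and with the mean of probe sets (0.0538), and STS was at 1.34 to 1.43 with another probe set when any of the same 6 arrays as in MCF-7:5C was left out or with a pseudocount of 1, and at 2.31 as the mean of its probe sets. Of 19 nuclear receptor coregulators 11 rose and 2 fell, with CARM1 at 1.31 (adjusted p = 0.0382, and adjusted p = 0.123 with an estimated correlation). The call was also lost on the deposited scale (median -0.019, adjusted p = 0.0789), with the filter at the 60th percentile (0.0806), with the mean of probe sets (0.0538) and without MCF-7 replicate 3 (0.0689) or MCF-7:2A replicate 2 (0.0521). PRMT1 differed by 1.33, but by -0.44 (adjusted p = 0.25) without probe sets ending in _s_at and _x_at. NCOA6 differed by 0.82, with its other probe set called in the opposite direction, by 0.47 (adjusted p = 0.343) on the deposited scale, and by -0.45 (adjusted p = 0.0879) as the mean of both probe sets. Adjusted over the list alone, the counts of these last 5 lists were the same. Without probe sets ending in _s_at and _x_at, the apoptosis, steroid and coregulator lists did not pass.

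Of 35 interferon response genes 15 rose and 5 fell, and the list did not pass (adjusted p = 0.0566, and adjusted p = 0.283 with an estimated correlation), with IRF9, part of an interferon-activated transcription factor, at 2.12. The list passed on the deposited scale (adjusted p = 0.0254), with no brightness filter (0.0318) and without MCF-7 replicate 3 (0.0491), MCF-7 replicate 4 (0.0496) or MCF-7:2A replicate 2 (0.0348). As above, part of it is not independent evidence. The other lists did not pass either. Luminal identity had 9 genes rising and 3 falling of 18 (AGR2), and passed on the deposited scale (adjusted p = 0.0311), under quantile normalization (0.0419), with no brightness filter (0.0405) and without MCF-7 replicate 1 (0.0281) or MCF-7:2A replicate 3 (0.0383). On the deposited scale the median of the luminal list was -0.121, above the -0.30 of all genes but under 0. The carcinoembryonic antigen family, not independent evidence, had 3 and 1 of 6 (CEACAM6) and passed on the deposited scale (adjusted p = 0.0174), and stromal and immune markers had 0 and 4 of 9 (limma; 1 and 4 at an unadjusted p under 0.05, fry downward with adjusted p = 7.34e-05, with COL1A1 at -2.20). Antigen presentation had 4 and 8 of 16 (PSMB10 at 1.72), basal markers 1 and 2 of 6 (ANXA1 at -2.80), and junctions 5 and 4 of 17 (PKP2 at 1.47). Cholesterol synthesis had 5 and 6 of 19 (ACAT2 at 1.38), proteases 3 and 2 of 18 (TIMP1), and fatty acid synthesis 2 and 8 of 19 (SCD at -2.87). Glutathione genes had 12 and 10 of 29 (GPX2 at 4.37), growth factor receptors 7 and 6 of 23 (GFRA1 at 3.28), mesenchymal genes 3 and 2 of 12 (TGFBI at 3.65) and inflammatory genes 2 and 5 of 20 (IL6ST at 1.82). At least 2-fold, 57.4% of the changed genes rose with the trimmed mean scaling and 25.8% on the deposited scale, where 2880 genes changed and the median over all genes was -0.30. As the mean of their probe sets, GPX2, IL6ST, COL1A1, SERPINA1 and PRMT1 differed by 2.78, 0.99, -1.39, 1.36 and 0.45, and ATF3 and RRM2 by -1.81 and 3.83 without probe sets ending in _s_at and _x_at.

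**Figure D2:**
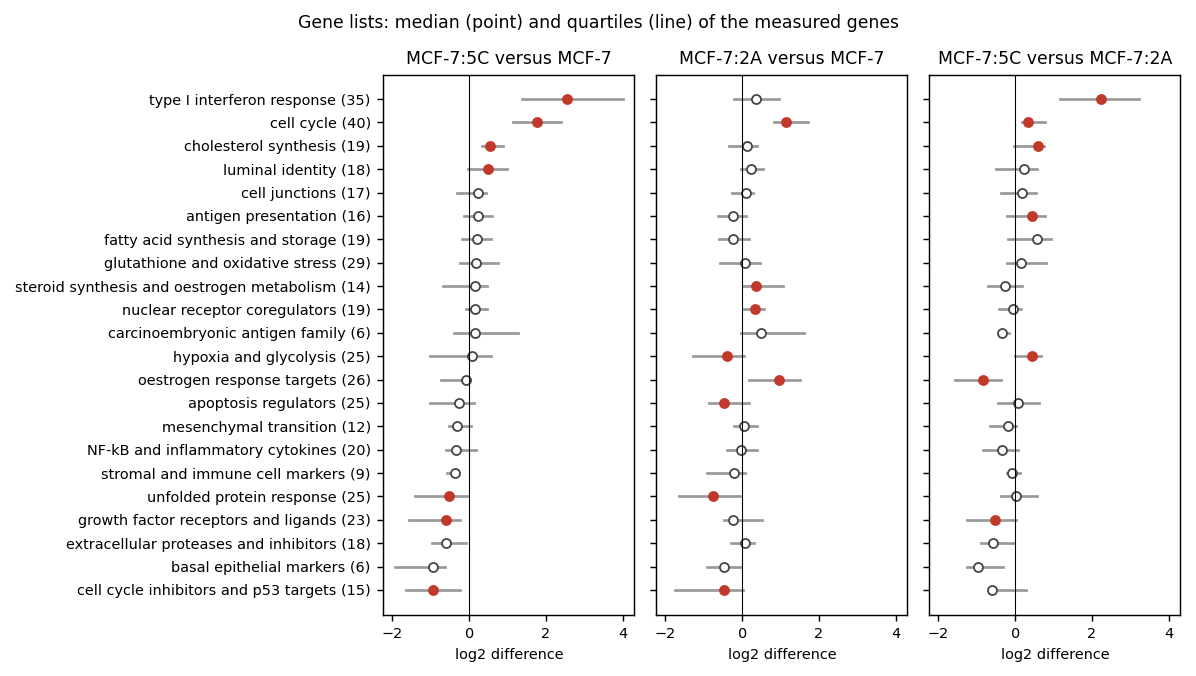
Points are the median log2 difference of the measured genes of each list (number measured in parentheses) and lines run from the lower to the upper quartile, for the 3 comparisons, with filled points for lists past camera with the preset correlation. The interferon list has a median of 2.55 in MCF-7:5C and 0.35 in MCF-7:2A against MCF-7.

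The direct comparison of MCF-7:5C with MCF-7:2A tests where the sublines differ. Interferon response genes were higher in MCF-7:5C than in MCF-7:2A. Known oestrogen targets were lower by camera with the preset correlation, but did not pass with an estimated correlation (adjusted p = 0.291). Fry, which does not compare a list with other genes, gave a downward direction (adjusted p = 2.36e-05). TM4SF1, a membrane protein gene, had a scaled signal of 22530 ± 1460 (SD, n = 3) in MCF-7:5C and 110 ± 99.4 (SD, n = 4) in MCF-7:2A, a log2 difference of 7.92 ± 0.51 (SE, adjusted p = 1.55e-08). PRSS23, an oestrogen-induced protease gene, had 13.4 ± 7.21 (SD, n = 3) against 5395 ± 632 (SD, n = 4), a log2 difference of -7.54 ± 0.20 (SE, adjusted p = 1.41e-12). In all, 6983 genes changed, and at least 2-fold 845 rose and 1434 fell. TNFRSF11B, CRISP3 and EFEMP1 rose by 6.50, 6.43 and 6.21 log2 units, and LGALS1, UPK3B and DACH1 differed by -7.17, -6.97 and -6.17. The lower signal of all of these genes but TM4SF1 and UPK3B lay under the filter level, with the same effect on their sizes.

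Of 35 interferon response genes 31 rose and 0 fell, and 33 rose adjusted over the list alone (adjusted p = 7.67e-20, and adjusted p = 0.00303 with an estimated correlation). At an unadjusted p under 0.05 0 fell, and fry gave an upward direction with adjusted p = 2.5e-09. BST2, IFI27 and OAS2 rose by 5.88, 5.66 and 5.10 log2 units, in a list that is in part not independent evidence. Of 26 oestrogen response targets 6 rose and 18 fell, or 19 adjusted over the list alone, with PGR at -4.17 and NRIP1 at -3.32 (adjusted p = 0.00106, and adjusted p = 0.291 with an estimated correlation). The PGR signal in MCF-7:5C lay under the filter level, so the size of its difference depends on the background and the pseudocount. Of 40 cell cycle genes 23 rose and 1 fell, and 26 rose adjusted over the list alone, with BIRC5, CDC25A and MAD2L1 at 1.75, 1.65 and 1.20 (adjusted p = 3.61e-05, and adjusted p = 0.2 with an estimated correlation). Of 16 antigen presentation genes 9 rose and 1 fell, with PSMB9, TAP2 and HLA-E at 2.01, 1.12 and 0.95 (adjusted p = 0.0116, and adjusted p = 0.2 with an estimated correlation). Of 19 cholesterol synthesis genes 11 rose and 2 fell, with LSS, STARD4 and MSMO1 at 1.75, 1.66 and 1.56 (adjusted p = 0.0116, and adjusted p = 0.2 with an estimated correlation). Of 25 hypoxia and glycolysis genes 14 rose and 4 fell, with BNIP3 and NDRG1 at 0.99 and 0.96 (adjusted p = 0.0128, and adjusted p = 0.291 with an estimated correlation). ENO1 differed by 1.13, but by -0.18 (adjusted p = 0.792) without probe sets ending in _s_at and _x_at, where HLA-E also lost its call (0.65, adjusted p = 0.199). Of 23 growth factor receptors and ligands 2 rose and 12 fell, with GFRA1 and ERBB4 at -3.99 and -3.35 and FGFR4 at 2.78 (adjusted p = 0.0313, and adjusted p = 0.224 with an estimated correlation). Adjusted over the list alone, the counts of the last 4 lists were the same. Calls were lost for antigen presentation and hypoxia on the deposited scale (adjusted p = 0.0757 and 0.0933) and without probe sets ending in _s_at and _x_at (0.348 and 0.0916), and for hypoxia and cholesterol synthesis under quantile normalization (0.112 and 0.0684). The cholesterol call was also lost with the filter at the 60th percentile (0.0578), and the growth factor call without those probe sets (0.0566), with no filter (0.0594), without a trend (0.0504) and without MCF-7 replicate 1 (0.0616) or MCF-7:2A replicate 1 (0.0507). As the mean of their probe sets, BIRC5, TAP2, HLA-E, ENO1 and ESR1 differed by 0.73, 0.61, 0.55, 0.58 and -1.46. ESR1 differed by -0.57 (adjusted p = 0.00845) and TFF1 by -0.36 (adjusted p = 0.00358), and both calls were lost on the deposited scale and under median centring, where TFF1 was 0.06 higher in MCF-7:5C, while quantile normalization gave -0.90 and -0.70. CEACAM6 rose by 1.18, and CEACAM5 differed by -0.11 (adjusted p = 0.714), with its other probe set called in the opposite direction and a difference of 0.57 (adjusted p = 0.0165) as the mean of both. At least 2-fold, 37.1% of the changed genes rose with the trimmed mean scaling, 49.9% under quantile normalization, 77.9% under median centring and 74.1% on the deposited scale. On the deposited scale 2610 genes changed. The median over all genes was -0.096, 0.045, 0.32 and 0.23 log2 units respectively.

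Changes against MCF-7 were also compared between the sublines. ADAMTS19, SH3BGRL and CDC45, a replication factor gene, were the largest rises shared by both, and OLFM3, SLC6A14 and TIMP1, a protease inhibitor gene, the largest shared falls. CDC45 rose by 4.75 log2 units in MCF-7:5C and 4.86 in MCF-7:2A, and TIMP1 fell by 3.56 and 4.99. The lower signal of all of these genes but TIMP1 lay under the filter level, so their sizes and order depend on the background and the pseudocount. At least 2-fold, 620 genes rose and 492 fell in both, 1112 in all, and 87 changed in opposite directions. Independent lists of these sizes would share 137 rises and 106 falls. Groups simulated without any change, with the MCF-7 arrays also simulated and used in both comparisons, shared 0 genes in all 100 simulations. With no gene changed, hardly any can pass the thresholds, so this count was fixed in advance and does not bear on the 1112. Across genes, which are not independent replicates, the differences had a Pearson correlation of 0.536 and a covariance of 0.394. Simulated unchanged groups gave a correlation of 0.464 and a covariance of 0.023, so that the covariances differed by 0.371. With the MCF-7 arrays split into separate controls of 2 and 2, 6 splits gave 1012 to 1082 genes changed the same way and a covariance of 0.353 to 0.381. These splits remove only the shared noise of single arrays. A trait common to all MCF-7 arrays, such as their higher actin ratio, enters both controls and is not excluded as a source of shared changes.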

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

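Tests of the dim shift as log2(value + 16), with unspiked controls, with stromal and immune markers and of the interferon list under another scaling were chosen after the results were seen. With 4 arrays in a group, an array was singled out when the gap to the nearest other array took up more of the range of the group than Dixon's 95% critical value, which chance does in about 1 in 20 groups. Among 216 groups of named gene values 15 did so, against 10.8 expected by chance. In MCF-7, the shares were 0.918 for MGP (replicate 3, 6.66 log2 units against 4.88 to 5.03), 0.848 for CRISP3 (replicate 3, 5.45 against 7.80 to 8.22), 0.833 for BIK (replicate 3), 0.882 for AGR2 (replicate 2, 9.00 against 7.63 to 7.79) and 0.913 for IRF9 (replicate 4). MCF-7 replicate 1 stood apart for CLDN4 (0.8291), LSS (0.831), HBEGF (0.864, at 7.87 against 9.42 to 9.67), HSD17B12 (0.927) and BIRC5 (0.845). In MCF-7:2A the shares were 0.839 for SH3BGRL and 0.847 for PSMB10 (replicate 4), 0.864 for STS (replicate 1), and 0.841 for GADD45B and 0.914 for SLC27A6 (replicate 2). MCF-7:2A replicate 2 also stood apart in the 3' to 5' ratio of GAPDH (0.844, at 0.027 against -0.11 to -0.092) and in the deposited trimmed mean (a share of 1, 188.8 against 500).

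Against MCF-7, 87 genes moved at least 2-fold in opposite directions in the sublines, so that a difference of over 2 log2 units between the sublines followed from their selection. Those named by the rule are given here as MCF-7:5C minus MCF-7:2A. TM4SF1 differed by 7.92, TNFRSF11B by 6.50, CRISP3 by 6.43 and EFEMP1 by 6.21, each risen in MCF-7:5C and fallen in MCF-7:2A. PRSS23 differed by -7.54, UPK3B by -6.97, DACH1 by -6.17, AKR1C3 by -5.41, PGR by -4.17, ERBB4 by -3.35 and BIK by -3.29, each fallen in MCF-7:5C and risen in MCF-7:2A. Of 6445 probe sets without a single named gene, which no comparison used, 2296 changed at least 2-fold in MCF-7:5C and 1105 in MCF-7:2A against MCF-7.

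After scaling, the MCF-7:5C arrays had lower medians than the MCF-7 arrays, with shifts as log2(value + 1) of -0.43, -0.48 and -0.014 in the dimmest, middle and brightest tertile of probe sets. One wrong factor per array would shift dim and bright probe sets alike, but the dimmest tertile shifted by -0.42 ± 0.08 (SD over 3 arrays) more than the brightest, outside the -0.28 to 0.28 seen between single MCF-7 arrays and the others (as log2(value + 16), -0.25 with -0.32 to -0.24 over the arrays, outside -0.20 to 0.14). Lower non-specific signal stays open, as does a biological difference between the lines, which was not tested. The 27 unspiked bacterial control probe sets differed by -0.28 ± 0.09 (SE) as log2(value + 1) and by -0.12 ± 0.06 (SE) as log2(value + 16), and on both scales the bound that would decide (-0.22 and -0.13) lies within 2 standard errors. In MCF-7:2A the same controls differed by 0.38 from MCF-7 with a shift of 0.078 in the dimmest tertile.

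The interferon list was higher in MCF-7:5C. RNA from stromal or immune cells stays open. Of 22 markers with no brightness filter 0 rose (limma, and 0 at an unadjusted p under 0.05) and 4 fell, with a median of -0.32, but 13 lay under the filter level, where dim probe sets in general were lower in MCF-7:5C. The scaling is argued against by the list median minus that of all genes, 2.40 under quantile normalization, the only alternative scaling that could move it in this comparison. A difference between the lines stays open, untested.

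The cell cycle list was higher in both sublines. Brightness-dependent array differences are argued against by 10000 random lists matched on mean signal, since the list median lay above 100% of them in both lines, with the highest random medians at 0.72 and 0.64. A model with the actin ratio of each array left 104% of the difference (1.82 ± 0.10 SE in MCF-7:5C and 1.36 ± 0.08 SE in MCF-7:2A). This argues against a bias towards the 3' end of the RNA that varies between arrays of a group. The actin ratios of MCF-7 (0.344 to 0.565) do not overlap those of the sublines (0.051 to 0.271). A bias that runs with the line is therefore not excluded. A faster-cycling culture or a difference between the lines stays open, since the labels give no growth rates. Wild-type MCF-7 in oestrogen-free medium was the reference for both sublines. Higher levels in the sublines therefore cannot be told apart from lower levels in MCF-7.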

How the results depend on the processing

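All alternatives but 3 were listed in advance. The other scale of the unspiked controls and of the dim shift and the list counts without MCF-7:2A replicate 2 were added after seeing the data, and the latter moved no count of risen or fallen members by more than 3. On the deposited scale, with 1 array at another level, 3326, 2880 and 2610 genes changed (MCF-7:5C against MCF-7, MCF-7:2A against MCF-7, MCF-7:5C against MCF-7:2A) in place of 7703, 6872 and 6983. The unscaled array widens the spread of MCF-7:2A in the shared estimate. Under the other scalings, pseudocounts, filters, probe set choices, variance priors and arrays in the fit, these counts, those at least 2-fold and the 1112 shared changes stayed within 1.5 times. The genes behind the counts were less stable. Of those called at least 2-fold, 71.3%, 94.5% and 65.2% were called again under median centring, in the same order of comparisons. These shares were 77.7%, 98.9% and 71.5% under quantile normalization. Without probe sets ending in _s_at and _x_at they were 72.2%, 72.4% and 72.5%. Leaving out each array gave 6883 to 7895, 6297 to 6802 and 5884 to 7365 changed genes.

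The number of lists past the threshold (7, 8 and 7) was 2, 2 and 1 with an estimated correlation and 19, 18 and 18 with fry, which does not compare a list with other genes. It was 2, 5 and 4 without probe sets ending in _s_at and _x_at, and 5 in MCF-7:2A with the mean of all probe sets. The cause was not tested. The estimated correlations were 0.007 for apoptosis regulators, 0.005 for coregulators and -0.024 for steroid synthesis, all under the preset 0.01. A higher correlation among their genes therefore does not account for the calls these lists lost in MCF-7:2A. For oestrogen targets, luminal identity and hypoxia the estimates were higher, at 0.193, 0.192 and 0.106. Leaving out each array gave 7 to 7, 7 to 9 and 6 to 7 lists. Values that changed sign, with a call in 1 or both settings, were those of TFF1 in MCF-7:5C against MCF-7:2A under median centring (0.059), NCOA6 in MCF-7:2A (-0.45) and CEACAM5 in MCF-7:5C against MCF-7:2A (0.57) with the mean of probe sets, and PRMT1 in MCF-7:2A (-0.44) and ENO1 in MCF-7:5C against MCF-7:2A (-0.18) without _s_at and _x_at probe sets. Without a call in either setting, CEACAM5 in MCF-7:5C against MCF-7:2A also changed sign on the deposited scale (0.23) and under median centring (0.31). The cell junction list had medians of 0.24 and 0.17 in MCF-7:5C against MCF-7 and MCF-7:2A, while fry gave a downward direction. The mean and the median of this list differ in sign. Calls of single genes were lost in 17 tests under an alternative (13 without and 4 with a change of sign), which cover 11 results, and in 2 tests without an array, both SERPINA1, where another of its probe sets was brightest. Of the tests of single lists under other settings, 904 kept a call or the lack of one, 43 lost a call and 41 gained one. A further 2, both of the cell junction list under fry, gained a call in the other direction. Most of the gains came from fry, which asks another question than camera. Where a list passed in neither setting, its direction was not compared.

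Replicate numbers did not pair the arrays. The 10 pairs with the same number had correlations of -0.054 to 0.064, and 1 of 11 arrays correlated best with its own number. With the replicate block 7303, 6712 and 6568 genes changed, 3211, 2141 and 2311 at least 2-fold, 1089 were shared, and 7, 8 and 7 lists passed. No detection calls were used here, so the limit set by signal over background is the brightness filter alone.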

Other observations

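The tests of neighbouring genes and of other splits were chosen before their results were seen; the planted runs of larger size were added after the first planted run was missed. Changes of 8-fold or more also separated the lines. Against MCF-7, 70 genes rose and 64 fell this far in MCF-7:5C and 43 rose and 31 fell in MCF-7:2A. Between the sublines, 48 were higher and 83 lower in MCF-7:5C. Of lists not past camera in the direct comparison, 10 of 19 fatty acid genes were higher and 4 lower in MCF-7:5C, and 4 of 18 proteases and inhibitors were higher and 10 lower. For 20 inflammatory genes 1 was higher and 8 lower, and for 14 genes of steroid synthesis 2 were higher and 6 lower. For 15 cell cycle inhibitors the counts were 4 and 8, for 25 genes of the unfolded protein response 10 and 8, for 25 apoptosis regulators 7 and 7, and for 19 coregulators 3 and 7. For 18 luminal genes they were 9 and 6, for 17 junction genes 5 and 6, for 29 glutathione genes 11 and 7, and for 12 mesenchymal genes 2 and 3. For 6 basal markers they were 0 and 3 (0 and 4 at an unadjusted p under 0.05), for 9 stromal and immune markers 1 and 1, and for 6 genes of the carcinoembryonic antigen family 1 and 0 (1 and 2 at an unadjusted p under 0.05).

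A hypothesis was that copy number differences between the lines may move neighbouring genes together. Of 13558 windows of 25 neighbouring genes (14110 genes placed), 87 had a median beyond the most extreme window of 100 shuffled orders in MCF-7:5C and 19 in MCF-7:2A. The widest run, 98 genes from GRB10 to GNAI1, had a median of -1.24 in MCF-7:5C, where 76 of them fell and 3 rose, and -0.24 in MCF-7:2A. These bounding genes were chosen after their values were seen. Array differences unrelated to the line are not excluded by the bound set in advance, because 1 of 3 contrasts of 2 against 2 MCF-7 arrays gave 10 windows and the other 2 gave 0, and the bound was 10% of the smaller count. The lowest window of that contrast was at -0.403, just beyond the lowest of its own shuffled orders at -0.392. In MCF-7:2A the lowest window was likewise just beyond, at -0.803 with shuffled orders down to -0.773. In MCF-7:5C it lay further out, at -1.541 with shuffled orders down to -0.92. The scan was also insensitive. On simulated data with 14110 genes and the spread of MCF-7:5C against MCF-7, a planted run of 60 genes gave 0 windows when shifted by -0.70 log2 units, 9 by -1 and 55 by -1.5, so runs with smaller shifts would be missed. No copy number was measured here.

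Other splits of the arrays were fitted in the same way. For MCF-7:5C against MCF-7, 1 of 35 splits, the real one, gave 7703 changed genes (highest other 3948). Likewise 1 of 35 gave 3233 at least 2-fold (highest other 1813). This is the smallest share that 35 splits can give, and it met the bound set in advance. Other splits mix lines within a group, which widens the spread, so the real split was likely to rank first. The splits argue against chance only to that extent, and cannot exclude array differences that run with the line. For MCF-7:2A, 1 of 35 gave 6872 (highest other 1), 1 of 35 gave 2141 (highest other 1) and 1 of 35 gave 8 lists (highest other 6). For MCF-7:5C against MCF-7:2A, 1 of 35 gave 6983 (highest other 2355) and 1 of 35 gave 2279 (highest other 971). Of 100 splits, the real one and random draws, 1 gave 1112 shared changes (highest other 1). The same limits hold for all of these counts. Chance cannot be excluded for the number of lists in MCF-7:5C against MCF-7, where 3 of 35 splits gave 7 or more (highest other 7). The same is true against MCF-7:2A, where 2 of 35 gave 7 or more (highest other 7).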
